A study of Shewanella decolorationis with 24 samples.

How the data were processed

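The labels describe RNA-seq of Shewanella decolorationis S12 with and without 60 mM Fe0 at 10, 30, 60 and 120 min, 3 independent experiments per condition, with ribosomal RNA removed before library preparation. Samples were grouped by treatment and time as their labels give them. The submitters' processing notes name TopHat2 2.0.11, SAMtools 0.1.18.0, Cufflinks 2.0.0 and Cuffdiff without a version; per the submitters' processing notes no role or order is given for these tools. The genome build is not given in the sources used here, other than through the contig names in the table.

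The authors deposited 1 table of the whole series, with 4219 genes and 206 blank rows that were left out. Per the file headers, its expression values are FPKM, 1 pooled value for each of the 8 groups. Per the file headers it also holds the log2 fold change of Fe0 over untreated at each time, which equals the log2 ratio of the deposited FPKM values within 1.3e-05 where both are above 0. An FDR-adjusted p-value per gene and time is deposited as well, per the file headers. The other deposited column, a yes or no mark of significance, was yes exactly where the FDR-adjusted p was under 0.05 and the absolute log2 fold change at least 1, with 0 exceptions. The smallest FDR-adjusted p in the authors' deposited table, 0.00101, was shared by all 4 times. Where 1 group was at 0, 13 log2 cells held inf and 24 a spreadsheet error in its place. Of these 37 cases none was called, and in 9 the other group exceeded 100 FPKM. Whether a listed 0 is a failed estimate or reflects few fragments was not tested.

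Contigs are named here by the number that ends their name in the table. Positions in the table count from 0 at the start and were written as 1-based positions. Of the genes, 3337 had a locus of their own and 882 shared 385 merged loci of up to 8 genes. In a merged locus each gene has its own value, but the split of reads between its genes is uncertain. For genes with their own locus, 99.3% of lengths were multiples of 3, so length is called coding length (median 837 nt). FPKM times length in kb, summed over these genes, ran from 748483 to 1369800 per group, so the deposited values are not scaled to each group's own total. FPKM keeps no library totals, and depth and counting precision are therefore unknown.

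The design set before the data were examined held that, with pooled values alone, the authors' FDR-adjusted p would serve as the call. Accordingly a gene was called at an FDR-adjusted p of at most 0.05 in the authors' deposited table, and its direction was taken from the log2(FPKM + 1) difference; that scale understates changes of genes with low values. No test between replicates was run, and neither the spread between replicates nor other splits of the samples entered, since no column of the table belongs to a single library. The genes named are, per time, at most 2 that rose and 2 that fell with the largest log2 difference among called genes with at least 10 FPKM in the higher group, the rule set for a table without gene names. The 35 gene lists fixed beforehand, and the further genes to be named whatever their result, could not be matched to the identifiers and were not tested.

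Overlaps of calls between times were set beside the product of both counts over all genes. Correlations and time courses used genes of at least 1 FPKM in any of the groups compared. Runs of at least 4 neighbouring genes on a contig called in the same direction were counted and set against 10000 random placements of as many calls. Each group was compared with the median of the other 3 untreated groups, over the genes called at its time. Trends with abundance or coding length were removed by subtracting the median of each of 10 bins of genes, with intervals of 95% from 2000 resamples of genes.

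These steps were tested on simulated data. Among 100 random sets of calls on the 4219 genes, 0, 1, 0 and 4 passed the 95th percentile of shuffles at the call numbers of 10, 30, 60 and 120 min, and 5 of 5 planted runs were found at each time. With 200 genes raised by 1 log2 in the Fe0 group of 30 min, the median departure came to 0.96 in that group, and with 200 lowered by 1 in the untreated group it came to -1.03 there. A rise of 1 planted in 200 random genes came out as 0.96 after the correction by coding length over 3337 genes. A rise planted in all genes of the bin with the longest coding lengths came out as 0.0003. That setting fills a whole bin, unlike genes picked for their difference. Alternatives covered a stricter FDR, a 2-fold minimum, filters at 1 and 10 FPKM, a pseudocount of 0.1 and median-ratio scaling. Added after seeing the data were scaling to a common sum, other untreated groups as control, omission of 30 min, genes above 0 in all groups, and other definitions of a run. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.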

Results

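Shewanella decolorationis S12 is a gammaproteobacterium that respires metals and azo dyes. The series asks how zero-valent iron (Fe0) acts on the cells while they reduce an azo dye. Cultures grew without oxygen in lactate medium with the azo dye amaranth, with 60 mM Fe0 or without it, and cells were collected at 10, 30, 60 and 120 min. RNA depleted of ribosomal RNA was sequenced from 3 independent experiments per condition, which gives 24 libraries in 8 groups. The values analysed here are 1 pooled FPKM (fragment abundance scaled by gene length and sequencing depth) per gene and group for 4219 genes on 69 contigs, so no value below carries a spread between replicates. The number of reads behind each value is unknown, because FPKM keeps no library totals and only 18 values between 0 and 1 FPKM could have shown what 1 fragment was worth. Summed over genes, FPKM came to between 1098190 (untreated, 30 min) and 2181600 (Fe0, 60 min) per group, while the median gene lay between 96.3 and 105 FPKM in all 8 groups. The table does not pair its gene identifiers with names or products, so genes are given by identifier and by position on the numbered contigs. Log2 differences below are Fe0 minus untreated, on the log2(FPKM + 1) scale. A gene counts as higher or lower where the FDR-adjusted p in the authors' deposited table was at most 0.05.

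At 10 min, 68 genes were higher and 32 lower with Fe0. The adjoining genes SHD_1044 and SHD_1045, which share 1 merged locus at 47532 to 49723 on contig 53, had the largest rises. SHD_1044 went from 20.04 FPKM without Fe0 to 124 FPKM with it, a log2 difference of 2.58, and SHD_1045 from 21.6 to 120 FPKM, a log2 difference of 2.42; the split of reads between the 2 genes is uncertain. SHD_1436, at 54017 to 54331 on contig 58, fell from 204 to 41.7 FPKM (log2 difference -2.27), and SHD_4204, at 983120 to 984285 on contig 76, fell from 76.8 to 18.7 FPKM (log2 difference -1.98), again within a merged locus of 2 genes. Against the median of the other 3 untreated groups the log2 differences were 2.58 for SHD_1044, 2.27 for SHD_1045, -3.12 for SHD_1436 and -1.40 for SHD_4204. Around SHD_4204, 8 of the 9 genes between 980240 and 988748 on contig 76 were lower, with a median log2 difference of -1.24 over the 9. All 6 genes between 11874 and 16837 on contig 49 were higher, by a median of 0.95. Over all genes of at least 1 FPKM the median log2 difference was 0.01, and 22 of the higher and 20 of the lower genes differed at least 2-fold. In the authors' deposited table the FDR-adjusted p was 0.00101 for each of the 4 named genes, the smallest value it holds at any time. That value occurs 588 times over genes and times, so it does not rank the named genes.

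At 30 min, 337 genes were higher and 59 lower with Fe0. SHD_0993, at 13022 to 13929 on contig 52 in a merged locus of 2 genes, stood at 383 FPKM without Fe0 and 3152 FPKM with it (log2 difference 3.04), and SHD_0989, at 11540 to 11872 on the same contig, at 361 and 2953 FPKM (log2 difference 3.03). The largest falls were those of SHD_1436, from 628 to 52.2 FPKM (log2 difference -3.56), and of SHD_4202, at 982105 to 983028 on contig 76, from 224 to 32.8 FPKM (log2 difference -2.73). Several stretches of neighbouring genes were higher together. They include 15 of 16 genes between 1307 and 9726 on contig 52 (median log2 difference 2.01), all 11 between 1 and 13559 on contig 16 (1.66), 9 of 10 between 56789 and 64823 on contig 50 (1.86), all 7 between 69098 and 82628 on contig 72 (1.33) and all 6 between 93021 and 99790 on contig 67 (1.28). All 9 genes between 980240 and 988748 on contig 76 were lower, by a median of -1.75. The genes higher at 30 min made up 22.0% of the summed FPKM with Fe0 and 8.66% without it. In the authors' deposited table the FDR-adjusted p was 0.00264 for SHD_0993 and 0.00101 for SHD_0989, SHD_1436 and SHD_4202.

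The untreated group of 30 min stood apart from the other untreated groups in these same genes. Over the 337 genes higher with Fe0, its level lay at a median of -1.34 log2 from the median of the untreated groups of 10, 60 and 120 min, while the Fe0 group of 30 min lay at -0.18. In the same genes that Fe0 group lay at a median of -0.88 from the median of the Fe0 groups of the other 3 times. The Fe0 level exceeded the median of the other 3 untreated groups in 93 of the 337 genes (27.6%). SHD_0993 is an example: without Fe0 it was at 2743, 6632 and 3783 FPKM at 10, 60 and 120 min, so that its 3152 FPKM with Fe0 at 30 min fell inside the range of those untreated values. Set against the median of the other untreated groups, the log2 differences of the genes named at 30 min were -0.26 for SHD_0993, -0.63 for SHD_0989, -2.16 for SHD_1436 and -1.43 for SHD_4202. For the 59 genes lower at 30 min the untreated group lay 0.63 above the other untreated groups and the Fe0 group at -0.54, and 43 genes (72.9%) were below them with Fe0. With the median of the other 3 untreated groups as the control, a comparison chosen after seeing the data, 136 of the 396 genes kept their direction at 30 min, against 91 of 100 at 10 min, 210 of 211 at 60 min and 703 of 715 at 120 min.

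**Figure D1:**
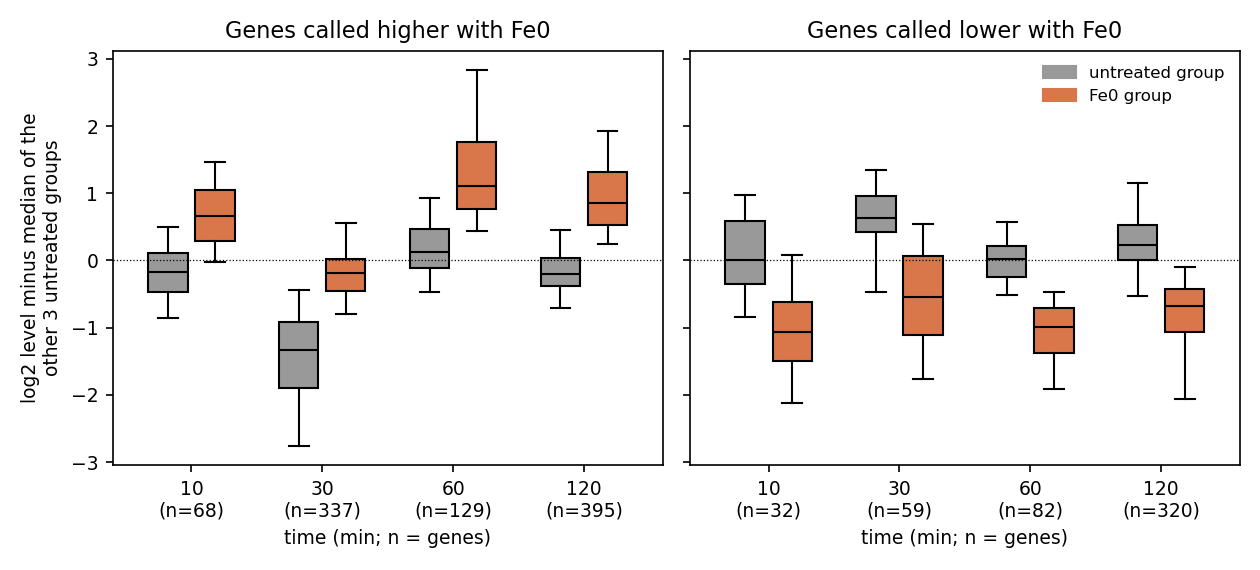
Levels of the genes called higher (left) and lower (right) with Fe0 at each time, in the untreated group (grey) and the Fe0 group (orange) of that time, as the log2 level minus the median of the other 3 untreated groups; boxes show quartiles and medians over genes, and whiskers run from percentile 5 to percentile 95, with genes beyond them not drawn. At 30 min the 337 higher genes have a median of -1.34 in the untreated group and -0.18 in the Fe0 group, whereas at 120 min the 395 higher genes have medians of -0.20 and 0.86.

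At 60 min, 129 genes were higher and 82 lower with Fe0. SHD_3522, at 197141 to 198049 on contig 76, rose from 175 to 1357 FPKM (log2 difference 2.95), and its neighbour SHD_3521, at 195569 to 197011, from 251 to 1901 FPKM (log2 difference 2.92). Both belong to a stretch of 8 genes between 190008 and 198952 that were all higher, by a median of 2.32; 7 were higher at 120 min and 0 at 10 min. At 30 min 7 of them were also called higher, when the median of the stretch was 129 FPKM with Fe0 and 43.7 without, against 119, 139 and 95.3 FPKM without Fe0 at 10, 60 and 120 min. On contig 49, 5 of the 6 genes between 11874 and 16837 were higher, with a median log2 difference of 1.52. SHD_1436 fell from 237 to 46.9 FPKM (log2 difference -2.31), and SHD_2569, at 10341 to 11321 on contig 69, from 3169 to 691 FPKM (log2 difference -2.20). Against the other 3 untreated groups the log2 differences were 3.64 for SHD_3522, 3.53 for SHD_3521, -2.95 for SHD_1436 and -1.84 for SHD_2569. The stretch between 980240 and 988748 on contig 76 had 8 of 9 genes lower, with a median of -1.21. In the authors' deposited table the FDR-adjusted p was 0.00101 for each of the 4 named genes.

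At 120 min, 395 genes were higher and 320 lower with Fe0, or 16.9% of all genes. A locus of their own was held by 376 of the higher and 297 of the lower genes, against 3337 of all 4219 genes. Genes of merged loci were thus called less often than the others. SHD_0783, at 14206 to 14697 on contig 49, rose from 688 to 6594 FPKM (log2 difference 3.26), and SHD_0786, at 16283 to 16837, from 267 to 1886 FPKM (log2 difference 2.82). SHD_0783 and SHD_0786 lie in the stretch of 6 genes between 11874 and 16837, all higher, whose median log2 difference was 2.23. SHD_3331, at 241696 to 242493 on contig 73, fell from 737 to 38.2 FPKM (log2 difference -4.23), and SHD_2912, at 81659 to 83323 on contig 71, fell from 3163 to 366 FPKM (log2 difference -3.11). Without Fe0, SHD_3331 stood at 143, 216 and 282 FPKM at the earlier times, and against the median of those groups its log2 difference was -2.46. Measured in that way it was 2.35 for SHD_0783, 2.27 for SHD_0786 and -2.45 for SHD_2912. Also higher were 15 of 16 genes between 1307 and 9726 on contig 52 (median 1.52) and 8 of 10 between 56789 and 64823 on contig 50 (1.53). All 9 genes between 122835 and 132510 on contig 67 were lower (median -1.25), as were all 6 between 72877 and 82218 on contig 56 (median -1.57). The higher genes held 37.0% of the summed FPKM with Fe0 and 19.2% without it. In the authors' deposited table the FDR-adjusted p was 0.00101 for each of the 4 named genes.

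The authors' values are not scaled to a common sum. Dividing each group by its own sum would move the median log2 difference by -0.18, -0.31, -0.40 and -0.50 at 10, 30, 60 and 120 min, a shift common to the genes of a time that the log2 differences given here do not include.

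**Figure D2:**
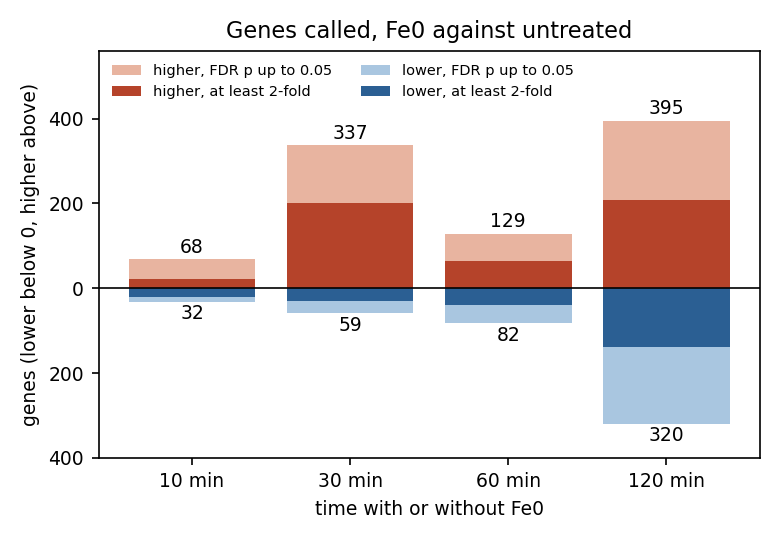
Number of genes higher (above 0) and lower (below 0) with Fe0 at 10, 30, 60 and 120 min, at an FDR-adjusted p of at most 0.05 (light bars, with their counts) and with at least a 2-fold difference as well (dark bars). The counts went from 68 higher and 32 lower at 10 min to 395 higher and 320 lower at 120 min.

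Across the 4 times, 957 genes were called at least once, and 227 were higher and 88 lower at 2 or more times; without 30 min these counts were 788, 114 and 78. SHD_1436 was lower at all 4 times, with log2 differences of -2.27, -3.56, -2.31 and -3.04, and was 1 of 19 genes lower throughout. SHD_4202 and SHD_4204 were among the others; the 9-gene stretch on contig 76 that holds them had medians of -1.24, -1.75, -1.21 and -0.86. SHD_1044 and SHD_1045 were among the 10 genes higher at all 4 times, and their log2 differences at 120 min were 1.27 and 1.09. SHD_3331 was lower at 10, 60 and 120 min, with log2 differences of -0.85, -2.11 and -4.23, and was not called at 30 min. SHD_2569 and SHD_2912 were called lower at 60 and 120 min and at neither earlier time. The 6-gene stretch on contig 49 had median log2 differences of 0.95, 0.46, 1.52 and 2.23, with 6, 2, 5 and 6 genes called.

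Genes called at 1 time were called in the same direction at another more often than independent lists would be. Between 60 and 120 min, 90 genes were higher at both times, where independent lists would share 12.1, and 72 were lower at both, where they would share 6.22. Between 10 and 120 min the counts were 40 higher, against 6.37, and 23 lower, against 2.43. Each time has its own untreated group, so these overlaps share no control group. They could still reflect a difference between cultures that lasted over the times, which was not tested. The expected counts treat all genes as equally likely to be called. As genes of merged loci were called less often at 10, 60 and 120 min, those counts are too low. Pearson's r of the log2 differences across genes was highest between 60 and 120 min, at 0.62, and between 0.28 and 0.46 for the other pairs; genes are not independent replicates. Over the 6 pairs of times the median r was 0.37; it was 0.24 with a pseudocount of 0.1 and 0.53 over genes above 0 FPKM in all groups. Between 10 and 60 min r was 0.12 with that pseudocount and 0.55 over genes above 0 FPKM in all groups. Differences between times were not tested, since no replicate values were used.

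Without Fe0, 381 genes (9.12%) differed at least 2-fold between 30 and 10 min, 337 of them lower at 30 min. At 60 min 98 genes (2.35%) and at 120 min 88 genes (2.10%) differed that much from 10 min. Across genes, the untreated group of 30 min correlated with the other untreated groups at Pearson's r of 0.908 to 0.928, and those other groups with each other at 0.971 to 0.976. On contig 52, the 16 genes between 1307 and 9726 had a median of 4485 FPKM without Fe0 at 10 min, 1162 at 30 min, 8586 at 60 min and 5728 at 120 min. With Fe0 their median was 7502, 4669, 17910 and 15697 FPKM. On contig 49, the median of the 6-gene stretch without Fe0 was 141, 185, 129 and 108 FPKM, and with Fe0 it was 314, 308, 406 and 463 FPKM. These comparisons between times carry no test.

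**Figure D3:**
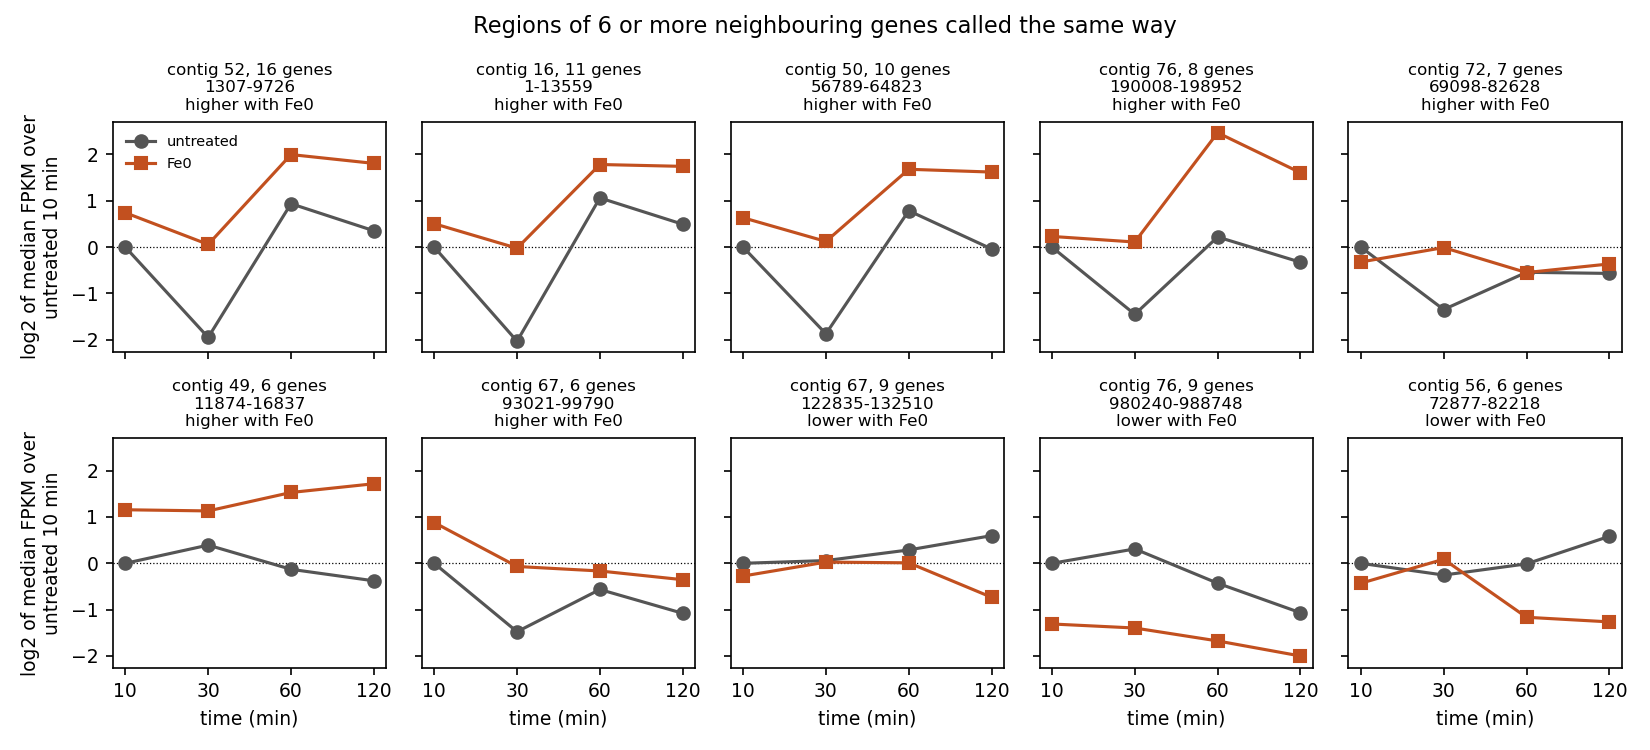
Time course of the 10 regions of 6 or more genes, each as the log2 of its median FPKM over that of the untreated group at 10 min, without Fe0 (grey circles) and with Fe0 (orange squares), against time in min. On contigs 52, 16 and 50 both the untreated and the Fe0 groups dip at 30 min, the untreated groups further. There the Fe0 groups lie above the untreated groups at all 4 times, while the 9-gene region of contig 76 lies lower with Fe0 throughout.

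The stretches named above were found by looking for runs of at least 4 neighbouring genes called in the same direction, an approach chosen after the table was seen to hold no gene names. Runs held 6, 93, 22 and 67 of the higher genes at 10, 30, 60 and 120 min, and 5, 13, 9 and 49 of the lower genes. The same numbers of calls placed at random genes 10000 times gave at most 4, 13, 4 and 14 higher genes and at most 0, 4, 4 and 16 lower genes in runs. The placements treated all genes as equally likely to be called, though at 10, 60 and 120 min genes of merged loci were called less often. The same held for the higher genes of 30 min, of which 313 of 337 had a locus of their own, against 3337 of all 4219 genes. Each of these 8 one-sided permutation tests gave p = 0.0001, the smallest the shuffles can give, and 0.0001 after Benjamini-Hochberg adjustment. Random placement also ignored that neighbours move together. Log2 differences of adjacent genes under 50 nt apart correlated at Pearson's r of 0.72 to 0.76. The p-values therefore speak only against calls placed independently of their neighbours, and not to why neighbours were called together. Joined over times, the runs made 21 regions of higher genes (125 genes) and 10 of lower genes (54 genes); 7 and 3 of them had at least 6 genes. Without the 30 min calls there were 13 and 10.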

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

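The comparison of groups with the other untreated groups and the scaling test below were chosen after the result was seen, whereas the tests by abundance and coding length were set before their outcome was. The direction of the Fe0 difference changed between times for 18 genes, which were called higher at 1 time and lower at another; the difference between times was not tested, and each group has 1 pooled value. Of these, 17 had 30 min on 1 side, and 12 were higher at 30 min and lower at 120 min.

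The 337 genes higher with Fe0 at 30 min may reflect the untreated group of that time as much as the iron. Only 27.6% of them had a Fe0 level above the median of the other 3 untreated groups, which fits an untreated group that lies apart; at 120 min the share was 99.5%. In the values as deposited no single scaling difference of that group remained. Its median departure was 0.011 log2 over all genes of at least 10 FPKM and -1.34 over these genes. The deposited values were already near a common median, with a median-ratio factor of 0.997 for that group, so scaling at an earlier step was not tested. Subtracting the median of each of 10 abundance bins took these genes' median log2 difference from 1.11 to 0.94 (95% interval 0.87 to 1.00). Bins of coding length took it from 1.11 to 1.097 (1.00 to 1.14) over the 92.9% with a length of their own. The medians subtracted ran from -0.13 to 0.44 for abundance and from -0.01 to 0.07 for coding length. The largest, 0.44 in 1 bin of abundance, lay below the median of 1.11 over these genes but was not negligible. As these genes were picked for their difference, a trend that reaches only part of a bin cannot be judged in this way. The Fe0 group of 30 min lay at -0.88 from the other Fe0 groups in these genes, a reference that holds the Fe0 groups of 60 and 120 min, while over all genes only 56 differed 2-fold between the Fe0 groups of 30 and 10 min (Pearson's r 0.978 across genes); a change of the untreated cultures, alone or with a smaller one under Fe0, and a difference in handling stay open with pooled values.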

How the results depend on the processing

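Alternatives without 30 min, with another control or reference time, with genes above 0 in all groups, with a common sum and with other runs were chosen after seeing the data. Requiring an FDR-adjusted p of at most 0.01 left 55, 240, 132 and 467 genes at 10, 30, 60 and 120 min, and requiring a 2-fold difference as well as the main threshold left 42, 229, 103 and 347; both follow from the stricter rule. Filters at 1 or 10 FPKM removed no called gene, and median-ratio scaling moved the median log2 difference by -0.05 to 0.02, so neither tests the calls, which rest on the authors' p. Against the other untreated groups, 136 of the 396 genes at 30 min kept their direction; with the 30 min group left out of that control, 91, 211 and 701 genes kept it at 10, 60 and 120 min. Genes higher at 2 or more times numbered 126 at the stricter FDR, 123 with the 2-fold minimum and 114 without 30 min, and genes lower at 2 or more times 50 and 42 under the first 2 of these. The median correlation between times was 0.24 with a pseudocount of 0.1, 0.38 for genes of at least 10 FPKM, 0.47 with Spearman's rho and 0.53 for genes above 0 in all groups. Leaving out genes with a listed 0 raised Pearson's r at every pair of times, to between 0.48 and 0.73. The smaller pseudocount, which widens differences from 0, lowered it at every pair. Genes with a listed 0 thus lowered r in the main setting. Against 60 min in place of 10 min, 11.7% of genes differed 2-fold in the untreated group of 30 min; the cause was not tested. Genes in runs, counted anew at each time, numbered 264 over all times. They numbered 155 at the stricter FDR, 166 with the 2-fold minimum and 158 without 30 min, which also left 13 regions of higher genes. Against the other untreated groups, the log2 differences of SHD_0993 and SHD_0989 at 30 min turned to -0.26 and -0.63, where the untreated group of that time lies apart, and 13 of the other named differences moved by over 0.1, among them SHD_3331 at 120 min from -4.23 to -2.46, SHD_0783 at 120 min from 3.26 to 2.35 and SHD_1436 at 10 min from -2.27 to -3.12. Scaling to a common sum moved all 16 named differences by over 0.1, as it shifts all genes of a time alike. Not run were another count-based tool, adjustment over all times or from unadjusted p, omission of replicates, and the gene lists, since the table used holds no counts, no unadjusted p, no single libraries and no gene names. No paired analysis was possible because the table gives 1 pooled value per group and no column for a single replicate. Depth is unknown and sets no limit that could be computed.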

Other observations

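With Fe0, 56 genes (1.34%) differed at least 2-fold between 30 and 10 min, 161 (3.85%) at 60 min and 177 (4.24%) at 120 min. Among the regions, the 9 genes between 122835 and 132510 on contig 67 had a median of 156, 192, 190 and 114 FPKM with Fe0 at 10, 30, 60 and 120 min, and of 189, 197, 230 and 285 FPKM without it. The 6 genes between 72877 and 82218 on contig 56 had medians of 1523, 2181, 915 and 854 FPKM with Fe0 at the 4 times and of 2051, 1721, 2035 and 3072 FPKM without it. The 8 genes between 190008 and 198952 on contig 76 had medians of 140, 129, 661 and 363 FPKM with Fe0 and of 119, 43.7, 139 and 95.3 FPKM without it, where the low untreated value is that of the 30 min group that stands apart. These time courses carry no test.

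Genes called higher were concentrated on contigs 49 and 52 at some of the times. Of 328 two-sided Fisher's exact tests (41 contigs of at least 20 genes, 4 times, 2 directions), 3 passed a Benjamini-Hochberg adjusted p of 0.05. Contig 49 held 13 higher genes among 85 at 10 min (15.3%, against 1.61% of all genes; Fisher's exact test, adjusted p = 4.95e-08). Contig 52 held 23 among 33 at 30 min (69.7%, against 7.99%; Fisher's exact test, adjusted p = 4.05e-16) and 20 among 33 at 120 min (60.6%, against 9.36%; Fisher's exact test, adjusted p = 5.08e-11). The 30 min calls of contig 52 are set against the untreated group that stands apart: in its stretch of 16 genes the median with Fe0 at 30 min was 4669 FPKM, against 4485, 8586 and 5728 FPKM without Fe0 at 10, 60 and 120 min, and SHD_0993 and SHD_0989 turned to -0.26 and -0.63 against the other untreated groups. Neighbouring genes move together, as the next values show, so these p-values are too small. The log2 differences of adjacent genes separated by less than 50 nt correlated across 921 pairs at Pearson's r of 0.72 to 0.76 at the 4 times, against 0.19 to 0.34 at gaps of 50 to 200 nt and 0.04 to 0.17 at gaps of 200 nt or more. The 488 pairs within a merged locus had r of 0.19, 0.60, 0.37 and 0.66 at 10, 30, 60 and 120 min, and random pairs lay between -0.02 and 0.02.

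The comparisons with the other untreated groups at 120 min were chosen after the result was seen; the tests by abundance, coding length and merged loci were set before their outcome was. Of the 395 genes higher with Fe0 at 120 min, the 376 (95.2%) with a coding length had a median of 609 nt, and of the 320 lower genes the 297 (92.8%) with one had a median of 921 nt. Subtracting the median of each of 10 length bins took the 376 higher genes' median log2 difference from 1.00 to 0.91 (95% interval 0.86 to 0.99). Bins of abundance took that of all 395 from 1.02 to 0.92 (0.88 to 0.97). The medians subtracted ran from -0.05 to 0.24 for coding length and from -0.06 to 0.33 for abundance. The largest of them lay below the uncorrected medians of 1.00 and 1.02 but were not negligible. A trend that reaches only part of a bin cannot be judged in this way, as the genes were picked for their difference. The Fe0 level exceeded the median of the other 3 untreated groups in 99.5% of these genes. As those include the group of 30 min, it was also set against the mean of the untreated groups of 10 and 60 min alone, which it exceeded in 98.2%. Both shares argue against an untreated group out of place at 120 min as the whole difference. A part is left open, as that untreated group lay at a median of -0.20 from the other untreated groups in these genes. A response to Fe0 remains a candidate explanation, as a hypothesis. Differences in handling between the Fe0 and untreated cultures of 120 min were not tested.

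Runs of neighbouring genes called the same way may reflect genes transcribed together. Added over times and directions, the runs held 264 genes, where a gene in runs at several times is counted at each. With genes of merged loci counted as not called, 216 of these counts were left, where the 95th percentile of shuffled calls was 8. Few calls lay in merged loci: 95.2% of the higher and 92.8% of the lower genes at 120 min had a locus of their own. The count could therefore hardly have fallen that far, and it shows only that most genes in runs had a locus of their own. Strand and transcript boundaries were not used here, so co-transcription itself was not tested.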
